A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

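RNA was sequenced from 2 cultures of BY4741 yeast, 1 untreated and 1 treated with 2.5 mM paraquat for 8 h, and the groups were taken from the treatment given in the labels. Per the labels' protocols, RNA came from a column kit and libraries followed standard Illumina methods. Whether poly(A) RNA was selected and whether the libraries keep strand are not given in the sources used here.

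The authors deposited 1 table with a normalized signal per gene and library, which is each gene's read count divided by 1 size factor per library. This reading comes from the values: every value in the table is a whole multiple, within 0.01 read, of a single step per column (1.10 normalized units in the untreated and 0.913 in the paraquat library), and the product of both steps is 1. The deposited log2 values equal the log2 ratio of the paraquat to the untreated signal in the same row, with a largest difference of 8.38e-05, so they are not shrunken. The deposited p-value and adjusted p-value columns were used as the authors gave them, per the file headers. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2, featureCounts and, for the authors' test, DESeq2 among the tools, without roles or order. The genome build and annotation are not given in the sources used here. With 1 library per group the authors' test has no replicates from which to estimate spread, and 130 unadjusted p-values in the authors' deposited table were under 0.05 where 307 would be if they were uniform.

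The table has 6143 rows. The 1 row without a name holds 0.00449% of untreated and 0.00675% of paraquat reads and was left out, which leaves 6142 named rows. Of these, 5999 matched a gene name or systematic name in the RefSeq R64 annotation and 143 did not. The annotation was used for names, overlaps and near-identical copies, and no coordinates are given because the authors' build is not named. A pair of symbols that had turned into calendar dates was kept under the text as deposited. Near-identical copies are genes with at least 95% identity over at least 80% of their length (245 genes), found with BLAST+ 2.17.0. Overlaps were searched on both strands. Neither search covered the 143 rows that did not match.

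Folds are the ratio of normalized values, and their 95% intervals are exact binomial (Clopper-Pearson) intervals of the read split between both libraries. The intervals cover counting error only and take reads as independent. PCR copies are not independent molecules, so the intervals may be too narrow even for counting error. Depth was 164909400 reads on named genes in the untreated and 165264107 in the paraquat library. The smallest named row held 3 reads in the untreated and 4 in the paraquat library. At this depth counting error is small for nearly all genes if reads are independent.

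The following were fixed before the data were examined: the sample groups, 44 gene lists, the naming rule, the tests and most alternatives. The design had 3 branches. Under the branch for a table with the authors' own test, genes with an adjusted p under 0.05 are counted, which gives 0. Under the branch for 1 library per group, genes at least 2-fold higher or lower with a mean of at least 50 normalized reads are counted, with no test. Both applied and both are reported, and the fold rule sets the named genes. Named genes are the 12 highest and 12 lowest past the fold rule, up to 4 genes per list (the 3 largest past 2-fold in the direction of the median and the 1 largest in the other direction, or the largest value where none passes), and a fixed set of superoxide, iron-sulfur and strain marker genes. This took 100 genes, of which 47 were higher, 35 lower and 18 within 2-fold, and 1 of them is not reported here.

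Each list of at least 4 measured genes was described by its median log2 change and the percentile of that median among 10000 random lists of the same size, matched on 10 classes of mean expression. A list was called shifted under percentile 2.5 or over 97.5. The list of mitochondrially encoded genes was not analysed here, which leaves 43 lists. Benjamini-Hochberg adjustment of the deposited p-values within each list gave counts adjusted over the list alone, which were above 0 for 2 lists.

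Alternatives were other adjusted p thresholds (0.01 and 0.1), no minimum fold, no minimum mean, recomputed adjustment, centring on the median gene, pseudocounts of 1 and 10, means in place of medians, unmatched random lists, a 99% range, and lists without their largest member or without near-identical copies. Scaling to total gene reads, protein-coding genes only, unadjusted p under 0.05 and a counting interval beyond 2-fold were chosen after seeing the data, as were 12 further gene lists in the closing part.

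Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene calls were tested on simulated counts with counting noise only, over 6142 genes. Of genes changed by log2 1.5, 100% of 100 were called with the right sign, as were 100% of 100 changed by log2 2.5. Of 5942 unchanged genes, 0 were called. List calls were tested on the measured log2 values, shuffled among genes of the same class of mean expression. There, 2 of 43 lists without an effect were called shifted, and 42 of 43 lists moved by 0.5 were called higher. Shuffling parts genes that are regulated together, so it does not show how often the list rule makes false calls on these data. The simulated counts hold no spread between cultures.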

Results

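Cells of the budding yeast strain BY4741, a haploid laboratory strain of mating type a, were grown in rich glucose medium to mid-log phase, and their RNA was sequenced without treatment or after 8 h in 2.5 mM paraquat. Paraquat is a herbicide that is reduced inside cells and hands electrons to oxygen, which forms superoxide. The comparison asks which transcripts differed between treated and untreated cells. The treatment labels give no time for the untreated culture, so time in culture cannot be told apart from paraquat. The untreated library held 164909400 reads on named genes and the paraquat library 165264107, with a median of 8441 and 10224 reads per gene. There was 1 library per group, so no difference reported here has a replicate check, and no p-value across genes was computed. Intervals on folds are 95% counting intervals of these 2 libraries that take reads as independent. They cover counting error only and say nothing about the spread between cultures.

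After paraquat, the iron regulon had the highest median change of the 43 gene lists analysed and the phosphate regulon the lowest. LSO1 (YJR005C-A), a small protein known from iron-starved cells, was 36.6-fold higher (32.4 to 41.5), from 287 to 10492 normalized reads. FIT1, a cell wall mannoprotein that retains iron-bearing siderophores, was 15.6-fold higher (14.9 to 16.3), and SRX1, the sulfiredoxin that repairs overoxidized peroxiredoxins, was 13.9-fold higher (13.1 to 14.8). TIR1, a cell wall mannoprotein of cells short of oxygen, was 13.5-fold lower (12.9 to 14.1), and the secreted acid phosphatases PHO12 and PHO11 were 7.81-fold (7.62 to 8.00) and 7.61-fold lower (7.25 to 8.00). PHO11 and PHO12 are near-identical copies, so the split of reads between them is uncertain.

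Of 5973 named genes with a mean of at least 50 normalized reads, 184 were at least 2-fold higher, 91 were at least 2-fold lower and 5698 lay within 2-fold. Among these, 30 were at least 4-fold higher and 8 at least 4-fold lower. The median log2 change was 0.28 in the lowest of 10 classes of mean expression and -0.31 in the highest. Genes of the lowest class thus started nearer to the 2-fold higher mark. Scaled to total gene reads in place of the deposited scaling, every log2 value moves up by 0.26 and the split becomes 312 higher and 44 lower, so values are given relative to the median gene. An adjusted p under 0.05 was reached by 0 genes in the authors' deposited table, where the smallest adjusted p was 0.999 and 130 genes had an unadjusted p under 0.05, 86 of them higher and 44 lower. The smallest unadjusted p in the authors' deposited table was 0.00310, for HSP12, and that of LSO1 was 0.123.

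**Figure D1:**
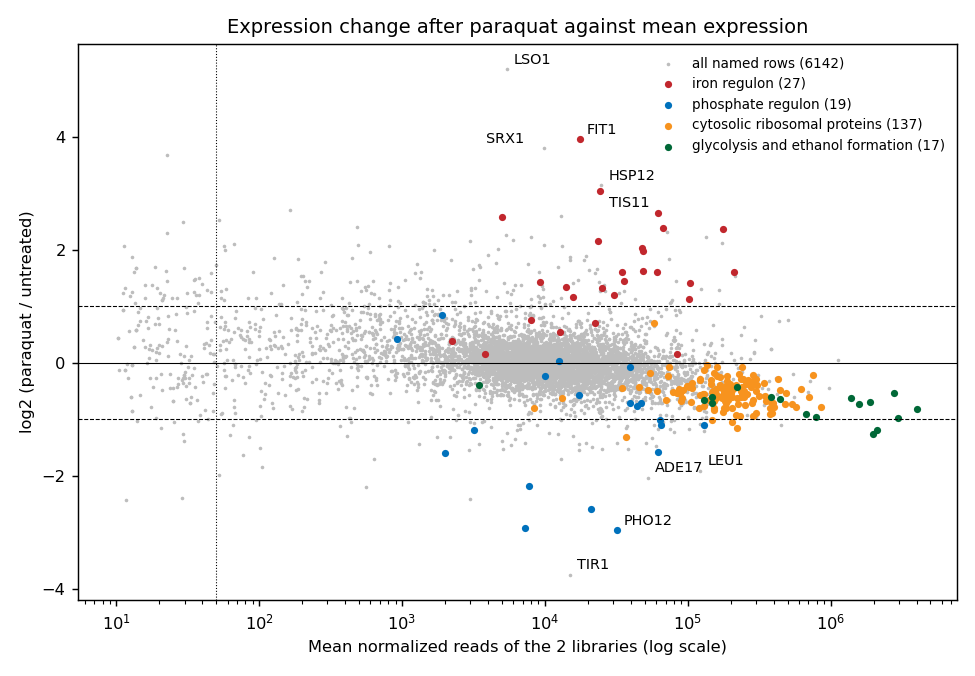
Each point is a gene, with its mean normalized reads over the 2 libraries on a log scale (x axis) and the log2 ratio of the paraquat to the untreated library (y axis). Dashed lines mark 2-fold and the dotted line a mean of 50. Points of the iron regulon (27 genes) all lie above 0, and those of glycolysis and ethanol formation (17 genes) all lie below 0.

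The remaining genes among the 12 highest were the small heat shock protein HSP12 (8.84-fold, 8.57 to 9.11), TIS11 (8.24-fold), the siderophore transporters ARN1 (6.26-fold) and ARN2 (5.24-fold), NCA3 (6.02-fold), the heme oxygenase HMX1 (5.95-fold), YOL162W (5.26-fold), the histidine tRNA gene tH(GUG)M (6.53-fold, 4.69 to 9.31) and YHR125W (5.78-fold, 3.28 to 10.96). The last pair rest on 40 and 14 untreated reads. The remaining genes among the 12 lowest were the acid phosphatase PHO5 (5.99-fold lower, 5.84 to 6.16), ANB1 (5.28-fold), DAN1 (4.58-fold), SPL2 (4.53-fold), the purine gene ADE17 (4.08-fold), LEU1 (3.76-fold, 3.73 to 3.80), the arginine tRNA gene tR(UCU)G3 (3.96-fold, 2.46 to 6.62), YOR314W (3.57-fold, 2.58 to 5.03) and the oxysterol-binding protein gene HES1 (3.26-fold). For tR(UCU)G3 and YOR314W the paraquat library held 23 and 50 reads. The tRNA genes tH(GUG)M and tR(UCU)G3 did not match the annotation by name, so the search for near-identical copies did not cover either. Whether other copies share their reads is not known, so both values are uncertain for a single gene.

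**Figure D2:**
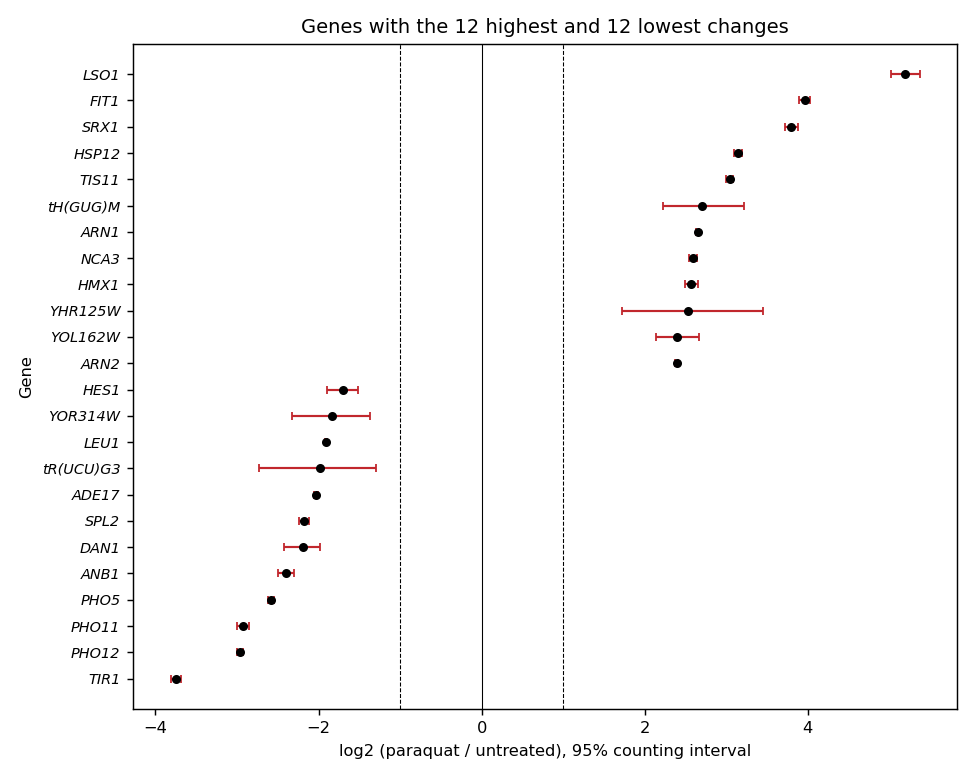
Log2 ratio of the paraquat to the untreated library (x axis) for the 12 genes with the highest and the 12 with the lowest ratio among genes with a mean of at least 50 normalized reads. Bars are 95% counting intervals, which are widest for YHR125W, tH(GUG)M and tR(UCU)G3, and dashed lines mark 2-fold.

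Superoxide and peroxide defence genes were higher as a group. Of 15 members 10 lay above 0, 4 were at least 2-fold higher and 1 was at least 2-fold lower, and the median log2 change was 0.67. Behind SRX1 came the glutathione peroxidase gene GPX2 (4.998-fold, 4.93 to 5.07) and the mitochondrial peroxiredoxin gene PRX1 (3.15-fold, 3.08 to 3.22). The superoxide dismutases stayed within 2-fold. SOD1, the copper-zinc enzyme, was 1.78-fold higher (1.78 to 1.79), but passed 2-fold when scaled to total gene reads. SOD2, the mitochondrial manganese enzyme, was 1.59-fold higher and the SOD1 copper chaperone CCS1 1.15-fold higher. CTT1, the cytosolic catalase, was 2.74-fold lower (2.63 to 2.85). This median lay at percentile 100 among 10000 random lists of the same size and matched expression, a description of these libraries that is used for each list.

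Genes of the thiol systems lay on both sides. The thioredoxin, glutaredoxin and glutathione list had a median of 0.29 over 22 genes (percentile 99.99), with 5 at least 2-fold higher and 1 lower. The glutathione transferases GTT2 (4.68-fold), GTO3 (4.01-fold) and ECM4 (3.37-fold) led it, and the cytosolic thioredoxins parted, with TRX2 2.48-fold higher (2.45 to 2.50) and TRX1 2.48-fold lower (2.44 to 2.52). Oxidoreductases and transporters linked to Yap1, the main peroxide-sensing transcription factor, had a median of 0.39 over 20 genes (percentile 99.99), with 5 at least 2-fold higher, among them the efflux pump gene ATR1 (3.54-fold), the nitroreductase-like gene HBN1 (3.33-fold) and AAD15 (3.97-fold). AAD15 rests on 21 and 100 reads and has a near-identical copy, AAD3. YAP1 itself was 1.39-fold higher. The oxidative pentose phosphate and NADPH list was not shifted (median 0.11, percentile 93.5), with ZWF1, its entry enzyme, 1.43-fold higher and NQM1 2.77-fold higher.

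The iron regulon, the genes that Aft1 and Aft2 switch on when iron is scarce, stood furthest above its random lists. All 27 members were above 0 and 21 were at least 2-fold higher, with a median of 1.45, a 2.74-fold difference, where random lists ranged from -0.26 to 0.06 (percentile 100). FIT1 led, followed by TIS11, an RNA-binding protein that speeds decay of transcripts for iron-using proteins, and ARN1. FET3, the ferroxidase of high-affinity uptake, was 3.05-fold higher (3.03 to 3.08), from 104023 to 317567 normalized reads. Of these genes 8 passed an adjusted p under 0.05 in the authors' deposited table when adjusted over the list alone, all higher, and 0 when adjusted over all genes. The authors' test compared 1 library with 1, so such counts say nothing about the spread between cultures. Copper genes (median 0.09 and mean -0.24 over 7, percentile 78.7) and zinc genes (median -0.18 over 10, percentile 7.03) were not shifted. In the copper list the transporter gene CTR1 was 2.25-fold lower and FRE7 2.14-fold lower, while 4 of the 7 copper genes lay above 0. ZRT3, a vacuolar zinc exporter, was 1.58-fold higher.

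Iron-sulfur enzymes were lower as a group, with a median of -0.52 over 17 genes (percentile 0), 11 below 0, 3 at least 2-fold lower and 1 at least 2-fold higher. LEU1, the isomerase of leucine synthesis, had the lowest log2 change at -1.91, then BIO2, biotin synthase, at -1.52, and homoaconitase LYS4 was at -0.97. ACO1, the mitochondrial aconitase, lay on the other side at 2.45-fold higher (2.43 to 2.47). Genes that assemble iron-sulfur clusters were not shifted (median 0.03 over 26, percentile 77.7), but would be called higher as a mean (0.18, percentile 98.8). The scaffold genes ISU2 (4.07-fold) and ISU1 (3.09-fold), which the iron regulon list also holds, were higher.

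Aconitase and isocitrate dehydrogenase separated from the rest of the tricarboxylic acid cycle. IDH1 (4.65-fold, 4.60 to 4.70) and IDH2 (4.33-fold, 4.29 to 4.37), the subunits of NAD-dependent isocitrate dehydrogenase, and ACO1 were the 3 members of the cycle list at least 2-fold higher, and 11 of 16 members lay below 0. The list's median was -0.30 (percentile 0.88) and its mean was 0.11 (percentile 92.8 among means), so median and mean differ in sign and the mean would not be called, nor the median with the 99% range. Retrograde response genes, which cells switch on when mitochondria falter, share these members and had a median of 0.91 over 10 genes (percentile 100), with 5 at least 2-fold higher, PDH1 (3.74-fold) included. Nuclear genes of the respiratory chain and ATP synthase were not shifted (median -0.01 and mean 0.07 over 33, percentile 58.6), with NDE1, the external NADH dehydrogenase, 1.91-fold higher.

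Amino acid synthesis genes differed by pathway. Lysine synthesis was lower (median -0.60 over 10 genes, percentile 0, 8 below 0), with LYS9 2.89-fold lower (2.83 to 2.94). Branched-chain synthesis was not shifted at its median (-0.33 over 12, percentile 21.97), although BAT1, the mitochondrial aminotransferase, was 2.24-fold lower beside LEU1, and the list would be called lower as a mean (-0.46, percentile 2.03) and against unmatched lists (percentile 0.19). Sulfur and methionine genes went both ways, with a median of -0.02 over 28 (percentile 63.9) and a mean of 0.23 (percentile 99.7 among means), so the mean of this list would be called higher. It held 6 genes at least 2-fold higher, led by STR3 at 4.80-fold, and 2 at least 2-fold lower, methionine synthase MET6 at 2.88-fold and homoserine dehydrogenase HOM6 at 2.53-fold. Arginine synthesis (median 0.05 over 10, percentile 74.7) and nitrogen catabolite-repressed genes (median 0.12 over 22, percentile 70.8) were not shifted, with ARG1 1.54-fold higher and CAR2 2.02-fold lower.

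Genes of glycolysis and of the cytosolic ribosome were lower as groups. All 17 genes of glycolysis and ethanol formation lay below 0, with a median of -0.70 (percentile 0.005), and the alcohol dehydrogenase gene ADH1 (2.38-fold) and the aldolase gene FBA1 (2.28-fold) were at least 2-fold lower. Of 137 cytosolic ribosomal protein genes 136 lay below 0, with a median of -0.54 against -0.36 to -0.23 for random lists (percentile 0), but 4 were at least 2-fold lower, RPS22B (2.48-fold), RPL9A (2.22-fold) and RPL30 (2.06-fold) among them. RPS22B overlaps an annotated noncoding gene, so its reads are uncertain. Scaled to total gene reads, ADH1, FBA1, RPL9A and RPL30 fell within 2-fold. The 467 other genes in the highest of 10 classes of mean expression had a median of -0.21, and the 25 most abundant genes took 20.9% of untreated and 15.5% of paraquat reads. Mitochondrial ribosomal protein genes had a median of -0.23 over 67 (percentile 0), with MRPL31 at -0.58, but a median of 0.03 when scaled to total gene reads. Ribosome biogenesis genes had a median of 0.02 over 42, above their matched lists (percentile 99), a call lost as a mean (percentile 95.1), against unmatched lists (percentile 65.05) and with the 99% range. It held RRN3, a polymerase I factor, at 1.97-fold higher.

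Hexose transporter and glucose-repressed genes were higher as groups. Hexose transporter genes had a median of 0.63 over 19 (percentile 99.98), 17 above 0, with HXT1 2.90-fold, HXT4 2.60-fold and HXT11 2.06-fold higher. HXT11 has near-identical copies. Glucose-repressed genes had a median of 0.36 over 23 (percentile 99.89), 20 above 0 and 3 at least 2-fold higher, which were the regulator ADR1 (3.68-fold), the succinate-fumarate carrier gene SFC1 (3.60-fold) and the regulator SIP4 (2.32-fold). Peroxisome and beta-oxidation genes were not shifted (median 0.01 over 21, percentile 20.2), although the carnitine carrier gene CRC1 was 3.87-fold higher.

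Ergosterol, heme and hypoxic genes were lower as groups. Ergosterol synthesis had 25 of 26 genes below 0 and a median of -0.44 (percentile 0), with ERG6 2.78-fold, ERG28 2.24-fold and ERG10 2.14-fold lower. Heme synthesis had 10 of 11 genes below 0 and a median of -0.48 (percentile 0), with HEM13, an oxygen-dependent oxidase, 2.90-fold lower (2.83 to 2.97). Hypoxic and anaerobic genes had a median of -0.38 over 21 (percentile 0), with 7 at least 2-fold lower, led by TIR1, ANB1 (the anaerobic isoform of a translation factor) and DAN1, while ROX1, the repressor of hypoxic genes, was 2.07-fold higher (2.03 to 2.11).

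The phosphate regulon, the genes for phosphate scavenging and storage, had the lowest median of the lists at -1.004, a 2.01-fold difference (percentile 0). Of 19 members 16 lay below 0 and 10 were at least 2-fold lower, and 3 passed an adjusted p under 0.05 in the authors' deposited table when adjusted over the list alone, all lower, against 0 when adjusted over all genes. In the other lists 0 genes passed either way. That test compared 1 library with 1, so these counts say nothing about the spread between cultures. SPL2, which restrains low-affinity phosphate uptake, also belongs to the phosphate regulon. Genes of a-type cells, the mating type of the strain, were lower too (median -0.58 over 7, percentile 0.11, 7 below 0), with AGA2 2.54-fold and BAR1 2.17-fold lower. The alpha-cell markers (median 0.29 over 4, percentile 73.1, STE3 1.63-fold higher), meiosis genes (median 0.28 over 18, percentile 75.6, with REC8 2.57-fold and SPO13 2.04-fold higher) and stationary phase markers (median 0.23 over 17, percentile 88.2, with SPG4 2.44-fold and SNZ1 2.24-fold higher beside HSP12) were not shifted. Stationary phase markers would be called higher as a mean (0.55, percentile 99.7) and against unmatched lists (percentile 98.8), and meiosis genes against unmatched lists (percentile 99.8).

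General stress genes were not shifted as a group. Msn2 and Msn4 targets had a median of 0.01 over 27 (percentile 67.6), with HSP12 the 1 member at least 2-fold higher and CTT1 the 1 at least 2-fold lower. Heat shock chaperones had a median of -0.02 and a mean of 0.05 over 27 (percentile 95.5), and HSP33, at 2.47-fold higher (1.63 to 3.85), rests on 31 and 92 reads and has near-identical copies. The proteasome list (median -0.10 over 33, percentile 64.8, RPN4 1.65-fold higher), DNA damage genes (0.10 over 21, percentile 87.3, PLM2 2.08-fold higher), histones (-0.06 over 11, percentile 82.9, HHT1 at -0.35) and cell cycle regulators (0.01 over 20, percentile 50.9, CLB6 1.65-fold higher) were also not shifted. Unfolded protein response genes were modestly higher (median 0.27 over 16, percentile 99.95), with 0 at least 2-fold higher and INO1, an inositol synthesis gene, at 1.69-fold. Trehalose and glycogen genes (median -0.24 over 20, percentile 1.75, GSY1 at -0.84) and autophagy genes (median -0.09 over 22, percentile 1.55, with ATG39, a receptor for nuclear autophagy, 2.44-fold higher) lay below their matched lists, but their medians turned to 0.02 and 0.17 when scaled to total gene reads. Both calls were also lost as means (percentiles 2.67 and 13.6) and with the 99% range, that of trehalose and glycogen without its largest member (percentile 3.25) and that of autophagy against unmatched lists (percentile 13.7). Drug resistance and polyamine export genes (median 0.04 over 19, percentile 90.5) held TPO2 at 2.09-fold higher and PDR15 at 2.71-fold lower, and cell wall genes (median 0.04 and mean -0.10 over 23, percentile 96.2, or 97.54, a call, without the largest member) held GSC2 at 2.75-fold higher and CWP1 at 3.23-fold lower.

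**Figure D3:**
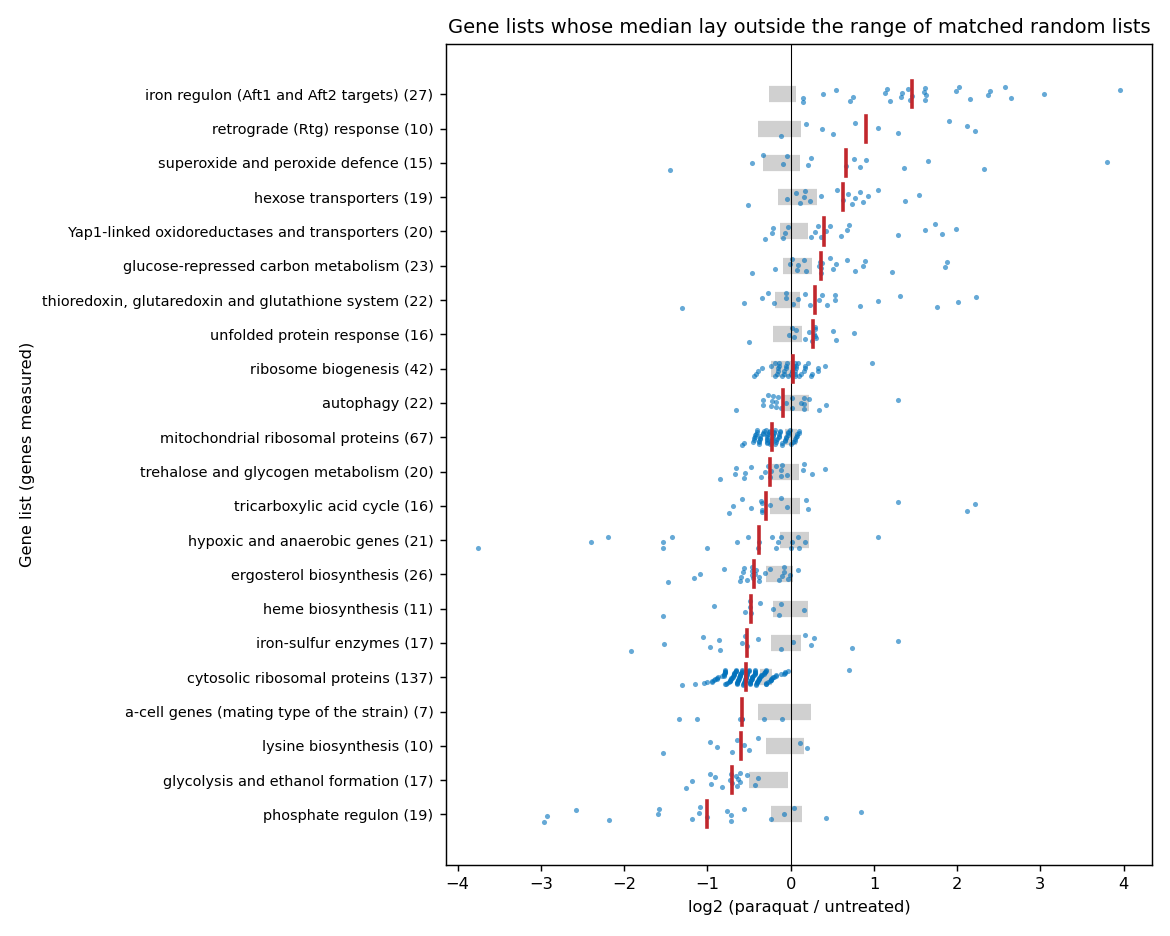
Log2 ratio of the paraquat to the untreated library (x axis) for each member (points) of the 22 lists whose median (red tick) fell outside the central 95% of 10000 random lists of matched expression (grey bar). Medians run from -1.004 for the phosphate regulon to 1.45 for the iron regulon.

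In total 22 of 43 lists were called shifted, 9 higher and 13 lower. By chance 2.15 would be called if the members of a list varied independently, as in the random lists. Genes that are regulated together do not, and some lists share genes, so 22 against 2.15 does not measure an effect of paraquat. The strain carries deletions at HIS3, LEU2, MET17 and URA3. HIS3 had 16302 and 13669 reads, but its deletion removes part of the gene, so these reads check nothing, and the other 3 loci were not analysed here. The test behind the p-values in the authors' deposited table compared 1 library with 1, so it compares these libraries, not the conditions.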

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

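The tests in this part were chosen only after the result was seen, except the search for genes that overlap or match HSP12.

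The row without a gene name was outside every comparison and held reads in both libraries, 7406 in the untreated and 11159 in the paraquat library, with no library that lacks RNA to set them against.

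Ribosomal protein and glycolysis genes were lower after paraquat, among genes whose abundance alone might lower them, since the highest of 10 classes of mean expression had a median of -0.31. If every abundant transcript had read lower alike, the 467 other genes of that class would share the medians of the list members within it, but their median lay above by 0.33 (0.27 to 0.39 by resampling genes) for 132 ribosomal protein genes and 0.50 (0.41 to 0.69) for 16 glycolysis genes. Scaling moves every gene by the same amount, so it cannot make this gap, but it sets where 0 lies, and the medians of the whole lists are -0.28 and -0.44 when scaled to total gene reads. Both lists had already lain below random lists matched on these classes, so a gap was largely known beforehand. It speaks only to a loss alike for all genes of the class. A loss that grows with abundance within the class was not tested. The -0.21 shared by other abundant genes stays unexplained. Class medians also differed over the whole range of mean expression. They were 0.28 in the lowest class, 0.18 in the next, -0.0085 in the 5th and -0.31 in the highest. The cause of this trend was not tested. An effect of paraquat, culture-to-culture variation and growth stage were not tested, with 1 library per group, and stay open.

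Small nuclear and nucleolar RNA genes were higher after paraquat, with 69 of 80 above 0 and a median of 0.60 (0.44 to 0.74 by resampling genes). Their share rose from 0.0690% to 0.145% of reads. This class was compared with 0, not with random lists of matched expression. Over all named genes, the lowest and next lowest of 10 classes of mean expression had medians of 0.28 and 0.18. How much of the gain is shared with equally abundant genes was not tested. The shorter 40 small nuclear and nucleolar RNA genes had a median of 0.40 and the longer 40 of 0.85, with a difference of -0.44 (-0.71 to -0.17). Within this class the gain was thus not larger for shorter RNAs. Both sets were higher and short mRNAs were not compared, so a general gain of short transcripts stays open. Less complete removal of RNAs without a poly(A) tail could account for the pattern, since 8 other noncoding RNAs had a median of 0.75 (0.49 to 0.89), with 8 of 8 above 0. Transfer RNAs also lack a tail, but their median of 0.0768 over 50 genes, 26 of them above 0, has a range of -0.17 to 0.51 and does not decide whether they share the gain. A real gain of these RNAs under paraquat was not tested and stays open.

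HSP12 was 8.84-fold higher although the general stress list that holds it was not shifted. The other 26 members had a median of -0.0249 (-0.27 to 0.14 by resampling genes), so the listed Msn2 and Msn4 programme did not rise jointly. That follows from the list not being shifted, so it is no separate test of what raised HSP12. Reads borrowed from an overlapping or near-identical gene are argued against by the 0 annotated genes that overlap HSP12 or match it. A regulator of HSP12 other than that programme might act here, but none was tested, and the difference rests on 1 library per group.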

How the results depend on the processing

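Scaling to total gene reads, protein-coding genes only, unadjusted p and the counting interval rule were chosen only after the result was seen. The counts of 184 genes higher and 91 lower became 2966 and 3006 with no minimum fold, 312 and 44 when scaled to total gene reads, and 86 and 44 at an unadjusted p under 0.05 in the authors' deposited table. The first and last follow from the rule itself, and the second from the uniform shift of 0.26. With no minimum mean they were 225 and 99, with a pseudocount of 10 177 and 89, for protein-coding genes 154 and 84, and with a counting interval beyond 2-fold 142 and 74. Lists with a member passing the authors' test went from 0 to 2 when adjusted over the list alone, as fewer genes are then tested. Between 18 (99% range) and 23 of 43 lists were shifted, against 22. With means over members 4 further lists were called and 4 no longer were, the tricarboxylic acid cycle included, and with unmatched random lists 3 further were called and 2 no longer were. The tricarboxylic acid cycle turned to 0.11 as a mean over members, because 3 members were far above the rest. Scaled to total gene reads, mitochondrial ribosomal proteins turned to 0.0307, trehalose and glycogen to 0.0159 and autophagy to 0.17. Of the 100 named genes, 85 stayed on the same side of 2-fold under that scaling. Another 4 passed it anew, SOD1 among them, and 11 no longer passed it, ADH1, FBA1, RPL9A and RPL30 among them. All 100 stayed under centring and both pseudocounts. Count tests that need replicates, with their own size factors and filters, and leaving out replicates were not run, since each group has 1 library. No paired analysis was possible because each group has 1 library. Depth limits few values, mainly genes under 50 normalized reads (169 rows).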

Other observations

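The 12 further lists in this part were chosen only after the changes of single genes were seen, and the test of purine genes was set out before its result was seen.

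Purine and one-carbon genes were lower after paraquat, with a median of -0.63 over 16 genes (percentile 0 among matched random lists), 13 below 0 and 2 at least 2-fold lower, ADE17 among them. Histidine synthesis (median -0.47 over 6, percentile 1.12) and aromatic amino acid synthesis (median -0.28 over 13, percentile 1.83) lay below their matched lists as well. When scaled to total gene reads, their medians are -0.22 and -0.02. Mitochondrial protein import genes had a median of -0.21 over 28 (percentile 0.21), which turns to 0.05 when scaled to total gene reads. Aminoacyl-tRNA synthetases (median -0.40 over 19) and translation factors (median -0.32 over 27) had 0 members above 0 under the deposited scaling. Yet both lay within the range of equally abundant genes (percentiles 17.9 and 28.6). Scaling to total gene reads turns their medians to -0.14 and -0.06.

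On the other side stood thiamine genes (median 0.30 over 16, percentile 97.6), the subtelomeric COS family (median 0.38 over 12, percentile 98.9) and maltose and isomaltose genes (median 0.45 over 11, percentile 98.0). The seripauperins (median 0.13 over 17, percentile 22.9), biotin genes (median 0.07 over 5, percentile 50.5) and vacuolar ATPase genes (median -0.07 over 17, percentile 77.2) were not shifted. Several of these families hold near-identical copies, so values of single members are uncertain. Transfer RNA genes with a mean of at least 50 had a median of 0.08 over 50.

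The phosphate regulon and the purine genes share the activator Pho2, which works with Pho4 at the former and with Bas1 at the latter. If lower Pho2 activity lay behind both, purine and one-carbon genes other than ADE17 and ADE5,7 should lie low as well. Their 14 members had a median of -0.57, at percentile 0.01 of matched random lists, with 3 above 0. The full list of 16 genes lay at percentile 0, so leaving out ADE17 and ADE5,7 could hardly give another outcome. It is therefore no separate test of Pho2. Other synthesis lists lay low too, such as lysine (median -0.60), heme (-0.48) and ergosterol (-0.44), though arginine (0.05) did not. A low purine list therefore does not single out Pho2. Lower activity of Pho2, which also serves purine genes with Bas1, is a candidate explanation and a hypothesis found in these libraries. Adenine and phosphate supply in the cultures, which could lower both groups separately, was not measured here.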
